A study of Homo sapiens with 2 samples.

How the data were processed

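RNA from 2 stable populations of Panc1, a human cell line from a pancreatic ductal adenocarcinoma, was hybridised to Affymetrix expression arrays. Such arrays read each transcript with probe sets, groups of short probes that lie mostly near the 3' end. Per the labels' protocols, both populations were kept under hygromycin, total RNA was column-purified, and biotin-labelled cRNA was made from it. There was 1 array per population.

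The deposited table holds 1 value per probe set and array for 54675 probe sets. The submitters' processing notes name RMA (robust multi-array average, which subtracts background, aligns the arrays' probe intensities by quantiles and summarises the probes of each set) without a version or settings. The values were taken as log2 intensities, since the deposited numbers run from 2.14 to 14.6 and are not centred per gene. No detection calls were used here. RMA compresses differences between dim probe sets, so a fold against a dim array is less certain than a fold between bright values.

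Probe sets were named through the platform annotation, whose symbols were compared with RefSeq gene IDs (GRCh38.p14). Of all probe sets, 41097 had 1 gene symbol, 1801 had several and were left unnamed, and 11777 were not named here. Of those with 1 symbol, 41043 matched a current gene ID and 0 had to be renamed. No genomic coordinates were used except the order of genes in that assembly. No array column was left unused.

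From these values the difference syk minus mock was computed per probe set. A gene took the value of its probe set with the highest mean over both arrays. Genes entered the counts when that mean was at or above 4.25, the 50th percentile over all probe sets, which left 12814 of 19775 genes. A gene was counted as differing at an absolute log2 difference of 1 or more, which is 2-fold. With 1 array per group there is no replicate error, so no p-value, standard error or confidence interval is given for any gene, and array, RNA preparation and population cannot be told apart. As a partial guide to precision, the pooled SD of the log2 difference between probe sets of 1 gene was 0.35 over the 6028 genes with several probe sets past the filter. It covers probe behaviour, transcript variants and cross-hybridisation, and no variation between cultures. The number of arrays limits the precision.

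A level for dim signal was chosen after the data had been seen. The 27 control probe sets against bacterial transcripts had medians of 2.80 (mock) and 2.91 (syk), and the highest value among them, 4.77, was taken as a floor for both arrays (the next highest probe set reached 3.61). Whether RNA for these controls was added is not given in the sources used here. A named gene past 2-fold with 1 value at or below the floor has its fold given as "at least", the brighter value against the floor, and no fold is given where both values lie at or below it, as in 969 of the 12814 genes. Differences given for a weakest or other probe set of a gene also use the floor. Counts and list medians use the measured values unless the floor is named.

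Gene lists (38, plus 8 lists of cell type markers) were fixed before the data were examined, and so were the filter, the threshold, the alternatives and the rule for naming genes. For each list with at least 3 measured members, the median log2 difference was set against 10000 random lists of the same size, each member being replaced by 1 of its roughly 200 neighbours in mean brightness. The percentile describes these 2 arrays and is no test of the conditions. Random lists hold unrelated genes, and co-regulated genes move together, so lists stand apart more often than the nominal 5%. A list is said to stand apart when its percentile is under 2.5 or over 97.5. The genes named are SYK, the 15 with the largest difference in each direction among genes past 2-fold whose probe sets past the filter all had the same sign, and up to 4 members per list with the largest absolute difference. Other names are marked where they occur.

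The calculation was tested on simulated data for the syk against mock comparison, with 12814 genes in the step. Of 100 genes changed by a log2 value of 1.5, 79 were recovered, and of 100 changed 8-fold, 100 were recovered. Each probe set kept its measured mean, and a change was the same in all probe sets of a gene. The filter and the choice of probe set could therefore not fail, and the recovery does not cover genes whose probe sets disagree. Of 12614 unchanged genes given the spread of the bulk of genes at their brightness, 354 (2.81%) crossed 2-fold. That spread came from the differences between these same arrays, so the share is no false-positive rate. Of 200 unshifted lists of 25 genes, 6.5% stood apart, and of 200 lists shifted by 0.5, 99.5% did.

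Alternatives were median centring of each array, removal of a loess trend of the difference on brightness (span 0.2), the mean or the median over a gene's probe sets, the use of probe sets ending in _at alone, no filter, a filter at the 75th percentile, a filter on the brighter array, and thresholds of 1.5-fold and 3-fold. An alternative for linear values was not needed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.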

Results

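Expression was measured in 2 Panc1 populations, a mock population carrying the vector alone and a population transfected with wild-type SYK, a non-receptor tyrosine kinase that acts downstream of immune receptors and integrins. The comparison asks which transcripts differ when SYK is put back into a pancreatic cancer line, and the series title describes the mock cells as drug-resistant. Each population had 1 array and no replicate, so every value below is a single measurement. The arrays had medians of 4.26 (mock) and 4.24 (syk) on the log2 scale and correlated at r = 0.98 across the 54675 probe sets, which are not independent replicates. The 18 hybridisation spike probe sets differed by a median of 0.01 (range -0.22 to 0.14). The ACTB control probe sets, a check on RNA integrity, had a 3' minus 5' difference of 1.95 on the mock array and 2.37 on the syk array. For GAPDH these differences were 0.19 and 0.32. This difference in 3' to 5' signal runs along with every contrast between the arrays.

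SYK itself was dim on both arrays. The brightest of its 4 probe sets read 4.27 on the mock array and 4.73 on the array labelled syk, a difference of 0.46, with both values at or below the highest bacterial control (4.77). That difference lay above those of 89.9% of the 1000 probe sets nearest in brightness. The other SYK probe sets differed by -0.09, -0.07 and -0.27, and lay at or below the 29.5th percentile of all probe sets on both arrays. SYK signal therefore gave no clear check of the labels, and each direction below rests on the labels alone. Where these probe sets lie relative to the introduced cDNA was not analysed here, and a probe set outside that cDNA would check nothing. Below, "the syk array" means the array labelled syk.

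Of 12814 genes, 930 (7.26%) differed at least 2-fold, 462 of them higher and 468 lower on the syk array. Of the 930, 238 had 1 of their values at or below 4.77, the highest signal of a bacterial control probe set, and 823 genes passed 2-fold with both arrays floored there. Folds of such genes are given below as lower bounds against 4.77, and these genes have no order among them. At least 8-fold differences were seen in 26 genes higher and 20 lower, and in 16 and 14 with the floor. Of the 15 genes named as higher, 13 had a mock value at or below 4.77. TNFRSF11B, which encodes osteoprotegerin, a secreted decoy receptor, was at least 66.3-fold higher (3.01 on mock and 10.8 on syk), with log2 differences of at least 3.76 and at least 6.05 in its 2 probe sets. MAL2, a membrane protein of apical transport in epithelia, was at least 52.0-fold higher. PTGS2, the inducible cyclooxygenase, was at least 13.5-fold higher, and the secreted matricellular protein CCN3 at least 10.4-fold, with at least 1.07 as the log2 difference of its other probe set. The heparan sulfate sulfotransferase HS6ST2 was higher by at least 8.01-fold and the stearoyl-CoA desaturase SCD5 by at least 15.2-fold, although 1 of its 3 probe sets lay at or below 4.77 on both arrays. The adhesion protein FLRT3 (a log2 difference of at least 3.87), the microtubule-associated MTUS1 (at least 16.1-fold, with at least 0.31 as its lowest probe set difference), the chemokine receptor CXCR4 (at least 9.19-fold) and the Wnt pathway transcription factor LEF1 (at least 12.7-fold) were also higher, as were BICC1 (at least 6.04-fold), PHLDB2 (at least 11.6-fold) and the interstitial collagenase MMP1 (at least 5.33-fold). BCAT1, a branched-chain aminotransferase, was 17.7-fold higher from a mock level of 7.32, and all 4 of its probe sets differed by at least 2.61. TENT5A was 13.2-fold higher from a mock level of 4.87.

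Of the 15 genes named as lower on the syk array, 6 had a syk value at or below 4.77. The neural cell adhesion molecule L1CAM was at least 25.4-fold lower by its brighter probe set (9.43 on mock and 4.25 on syk), while its second probe set differed by -0.57. The LIM-domain proteins CRIP1 and CRIP2 were 29.5-fold and 9.18-fold lower. The interferon-induced genes among the 15 were IFIT3 (14.3-fold), IFIT1 (13.1-fold), IFITM1 (10.2-fold) and IFIT2 (9.06-fold). The microtubule-associated NAV1 was 13.9-fold lower, with 6 probe sets between -3.79 and -0.11. The transcription factors PAX2 (at least 9.02-fold), TCF7L1 (at least 6.58-fold) and TOX2 (8.97-fold) were lower, as were the pseudokinase TRIB2 (at least 7.93-fold), the epithelial sodium channel subunit SCNN1A (at least 7.53-fold, with a lowest absolute difference of -0.02 among its 3 probe sets), the neurotrophin BDNF (at least 5.62-fold) and the mitochondrial protein EFHD1 (8.58-fold). With the floor the other PAX2 probe set differed by -0.13. Of the 441 genes past 2-fold with several probe sets, 382 (86.6%) had the same sign in all of them, against 58.9% of the 5587 such genes under 2-fold. Genes under 2-fold include those near 0, whose sign turns easily, so part of this gap is built in. All probe sets of a gene read the same RNA on the same arrays, so their agreement cannot separate population from preparation or array. In the simulation 2.81% of genes left unchanged crossed 2-fold, against the 7.26% seen. The simulated noise was normal, with a spread taken from the differences between these same arrays. The 2.81% is thus no false-positive rate, and the gap to 7.26% does not count real changes. Averaging a gene's probe sets gave 562 genes past 2-fold, and the filter at the 75th percentile gave 486.

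**Figure D1:**
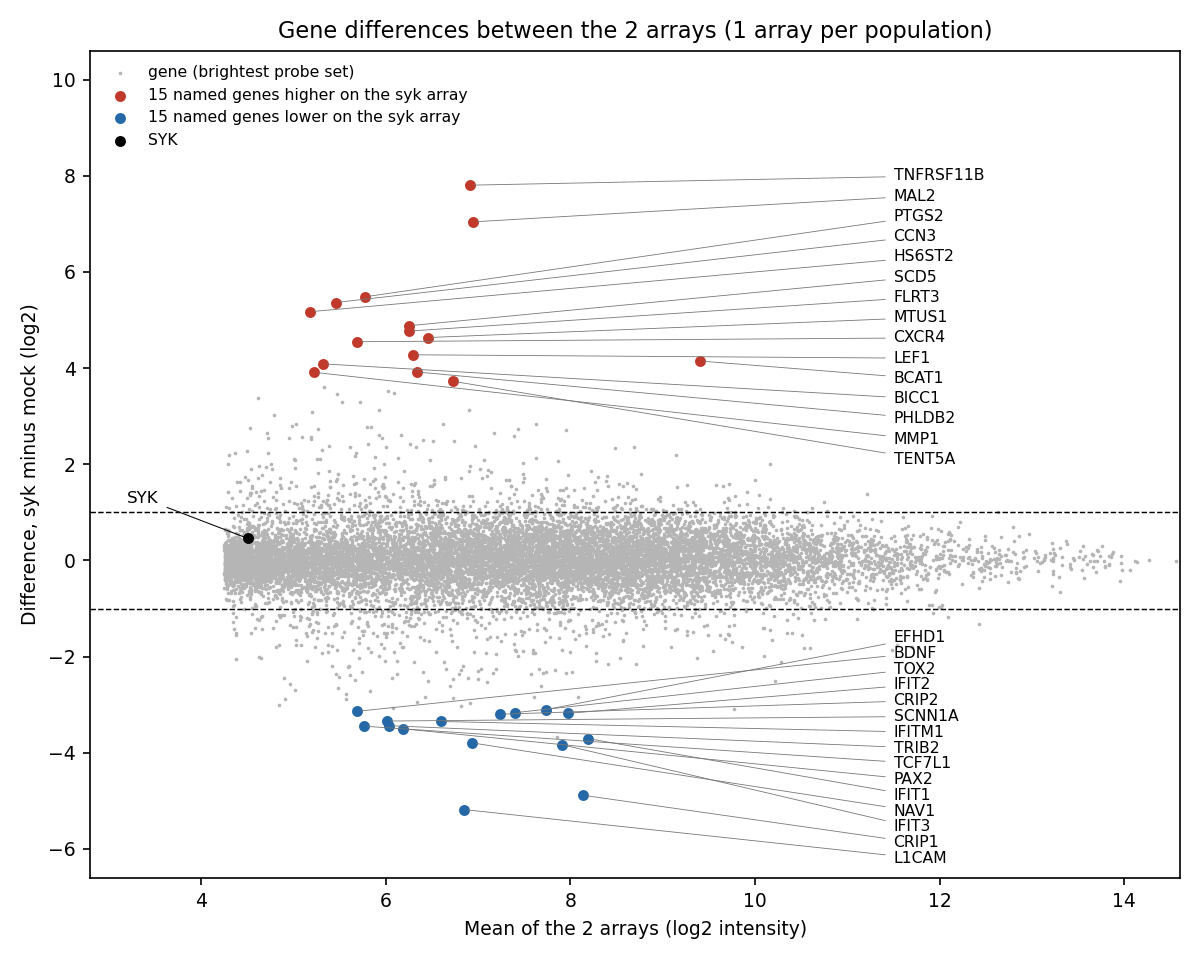
Difference syk minus mock (y axis, log2) against the mean of both arrays (x axis, log2 intensity) for 12814 genes, 1 grey point per gene, with dashed lines at 2-fold. The 15 named genes higher on the syk array (red) and the 15 lower (blue) are drawn at their measured differences, which for 13 of the higher and 6 of the lower rest on 1 value at or below 4.77 and have no order. SYK (black) lies at 0.46.

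Interferon-stimulated genes were lower on the syk array as a group. Of 27 measured members, 14 were at least 2-fold lower (13 with the floor), 1 was at least 2-fold higher and 12 were under 2-fold, with 26 of the 27 below 0. The median difference was -1.01, below each of the 10000 random lists matched on brightness, whose central 95% ran from -0.18 to 0.24. The largest differences were those of IFIT3, IFIT1, IFITM1 and IFIT2. The exception was ISG20, an exonuclease, at 3.10-fold higher, named after its value was seen. IFIT3 and IFIT2 are paralogs of IFIT1, and cross-hybridisation among them was not excluded. Antigen presentation genes had a median of -0.31 over 18 members, of which 0 passed 2-fold, below 99.8% of random lists. The immunoproteasome subunit PSMB9 was 1.93-fold lower and the peptidase ERAP2 1.87-fold lower. With probe sets ending in _at alone, antigen presentation no longer stood apart (percentile 2.88).

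Genes of sterol synthesis were also lower. All 19 measured members of the cholesterol list were below 0, 8 of them at least 2-fold lower, and the median of -0.90 lay below each of the random lists. LSS, which makes lanosterol, was 3.42-fold lower, the sterol-regulated INSIG1 2.92-fold, DHCR7, which carries out the last step of the pathway, 2.76-fold, and the acetyl-CoA acetyltransferase ACAT2 2.55-fold. The weakest INSIG1 probe set differed by -0.83, and 1 LSS probe set lay at or below 4.77 on both arrays. In the fatty acid synthesis list 4 of 15 members were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.66 that lay below each of the random lists. The desaturase FADS2 (5.02-fold) and fatty acid synthase, FASN (2.70-fold), were lower, while SCD5 (at least 15.2-fold) and the elongase ELOVL6 (at least 2.42-fold) were higher. The dimmer FADS2 probe set lay at or below 4.77 on both arrays. With probe sets ending in _at alone the fatty acid list had a median of -0.26 over 10 members and did not stand apart (percentile 3.92).

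The cell cycle lists differed in how far they moved. G1/S genes had a median of 0.54 over 36 members, above each of the random lists, with 31 members above 0, 7 at least 2-fold higher and 0 at least 2-fold lower. The median was 0.35 with the mean over probe sets, and the list still stood apart. Cyclin D2, CCND2, was at least 5.16-fold higher from a mock value of 3.53. The replication licensing factor CDC6 was 2.78-fold higher, cyclin E2 (CCNE2) 2.35-fold and the primase subunit PRIM1 2.28-fold. G2/M genes had a median of 0.05 over 36 members, of which 0 passed 2-fold, at the 57.2th percentile of random lists. The bright members PTTG1 and TPX2 differed by 0.26 and 0.34, and the largest G2/M difference was that of CDC25B, a phosphatase that activates mitotic kinase, at 1.82-fold lower. The difference between the lists was not tested. CDK inhibitors and p53 targets had a median of -0.21 over 25 members, with 3 at least 2-fold lower, among them SFN (14-3-3 sigma) at 3.40-fold and TP53INP1 at 2.37-fold, and with ZMAT3 2.19-fold higher. This last list stood apart at the 2.15th percentile, and 5 of 8 alternatives ended that.

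**Figure D2:**
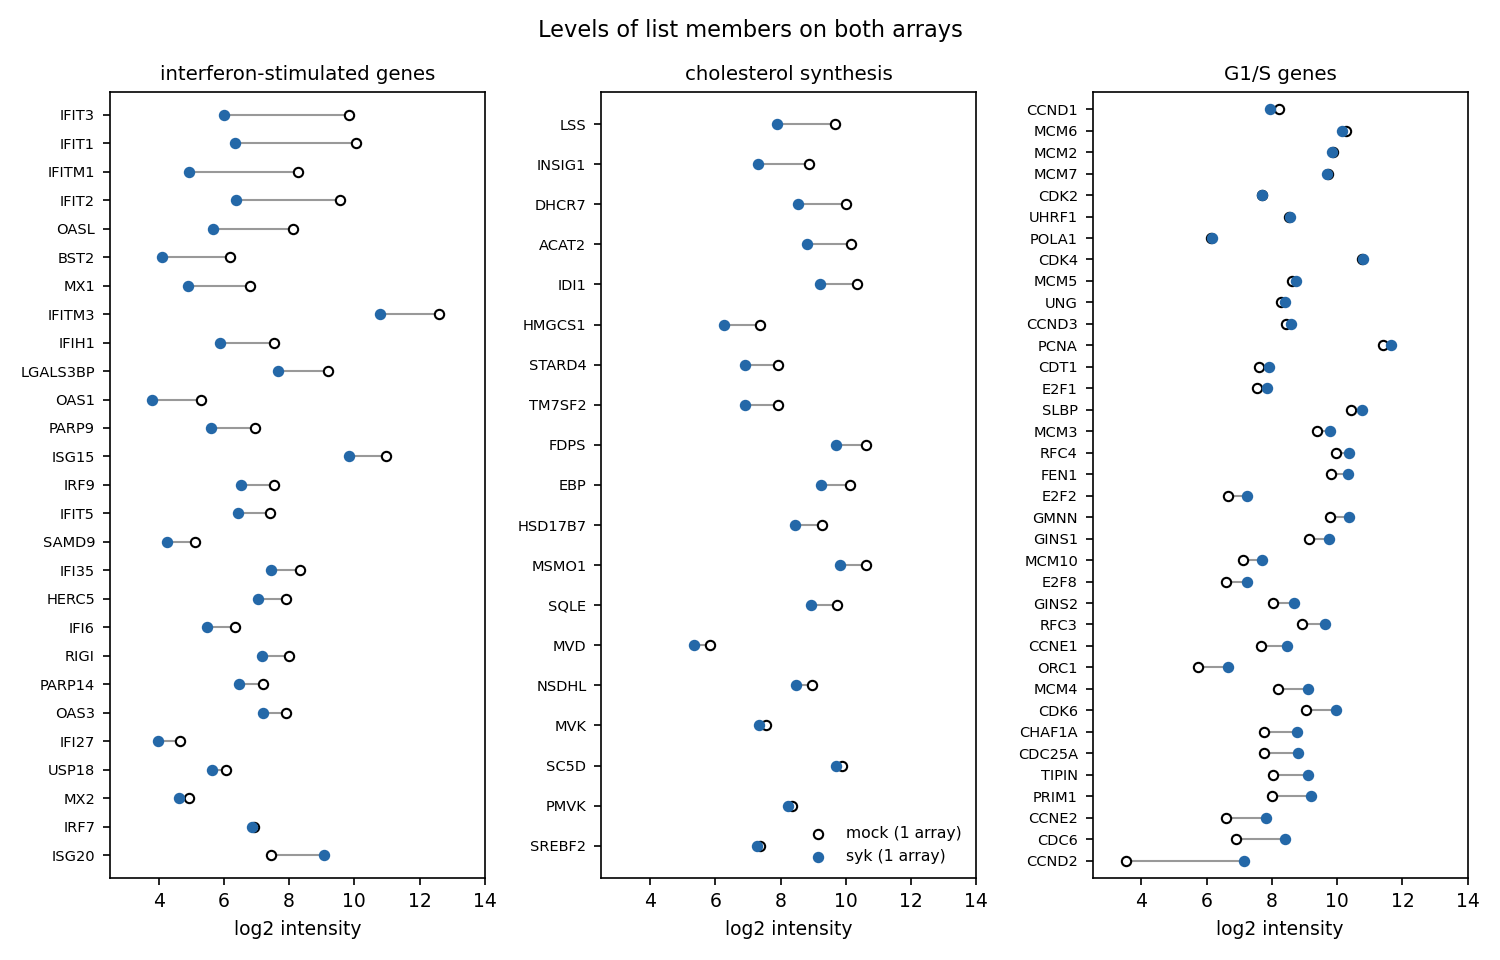
Level of each measured member (log2 intensity, x axis) on the mock array (open circles) and the syk array (filled circles) for 3 lists, sorted by difference. Of the interferon-stimulated genes 26 of 27 lie lower on the syk array, of the cholesterol synthesis genes 19 of 19, and of the G1/S genes 31 of 36 lie higher.

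Extracellular matrix genes, S100 proteins and annexins, and cytoskeleton genes were lower on the syk array as lists, while metalloproteinases, plasminogen activation genes and integrins did not stand apart. Of 23 extracellular matrix genes, 8 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -0.60 below each of the random lists. That median was -0.35 with the mean over probe sets, -0.30 with their median, -0.25 without a filter and -0.96 with the filter at the 75th percentile, and the list still stood apart. The collagen chain COL5A2 was 7.20-fold lower and the proteoglycan SDC2 3.34-fold lower, while COL13A1 was 5.62-fold higher, although the lowest of its 3 probe sets differed by 0.16. NID1, a basement membrane protein, was 5.50-fold lower by its brightest probe set, and another of its 3 probe sets lay at or below 4.77 on both arrays. The metalloproteinase list had a median of -0.05 (between -0.24 and 0.04 under the alternatives) and did not stand apart (27.4th percentile), but its members parted: MMP1 was at least 5.33-fold higher, whereas MMP2, a gelatinase, was 7.18-fold lower, the metalloproteinase ADAM19 at least 2.26-fold lower and the inhibitor TIMP2 2.02-fold lower (the weakest of its 3 probe sets at -0.27). The plasminogen list did not stand apart (median 0.06, between -0.11 and 0.08 under the alternatives), with SERPINI1 5.10-fold higher and S100A10, a plasminogen receptor subunit, 2.51-fold lower. Among 16 integrins the median was -0.06 (between -0.09 and -0.02 under the alternatives) and ITGB4, the beta subunit of hemidesmosomes, was 3.73-fold lower, although 1 of its 3 probe sets differed by -0.11. S100 proteins and annexins had 16 of 17 members below 0 and a median of -0.80, below each of the random lists. ANXA6 was 3.96-fold lower, S100A4 3.61-fold and S100A13 3.50-fold. Without a filter the median of this list was -0.38, still below each of the random lists. Cytoskeleton and motility genes had a median of -0.27 over 33 members (0.15th percentile), with the myosin light chain MYL9 3.11-fold lower, GSN (gelsolin) 2.03-fold lower and the actin-associated PALLD 2.19-fold higher. With the floor the weakest probe sets of MYL9 and GSN differed by under 0.01.

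Epithelial markers went both ways. Of 29 members, 5 were at least 2-fold lower and 3 at least 2-fold higher. E-cadherin, CDH1, was at least 2.98-fold lower (6.34 on mock and 3.47 on syk), while the desmosomal DSP was 6.64-fold higher, the tricellular junction protein LSR at least 5.51-fold and MAL2 at least 52.0-fold. The other genes at least 2-fold lower, named after their values were seen, were the tight junction claudins CLDN7 (5.77-fold, 8.36 on mock and 5.83 on syk) and CLDN4 (5.16-fold, 7.98 and 5.61), and KRT19 (2.72-fold) and MUC1 (2.06-fold). The median of -0.23 stood apart at the 0.94th percentile, and 3 of 8 alternatives ended that, most of all probe sets ending in _at alone (-0.003, 45.7th percentile). Mesenchymal markers had a median of -0.09 over 15 members (19.1th percentile) and did not stand apart. The list did stand apart with the mean over probe sets (-0.35), the filter on the brighter array (-0.49) and the filter at the 75th percentile (-0.66). Among its members were S100A4 and COL1A1 (2.13-fold) lower and FN1 (fibronectin, 2.29-fold) higher. The weakest probe sets of COL1A1 and FN1 differed by -0.09 and at least 0.02.

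In the lists chosen for drug response, genes past 2-fold went both ways. Among 18 ABC transporters, 1 passed 2-fold, ABCB10 at 2.06-fold lower, and the median was -0.22, at the 2.5th percentile. The list stood apart after loess (-0.24), with the filter on the brighter array (-0.27), with the filter at the 75th percentile (-0.38) and with the floor (-0.21, percentile 1.09), and its median was -0.12 with probe sets ending in _at alone. ABCC1, a drug efflux pump, was 1.85-fold lower. The nucleoside transporters SLC29A2 and SLC29A1, which carry nucleoside analogues into cells, were 2.52-fold (by 1 of 3 probe sets, another being at or below 4.77 on both arrays) and 2.40-fold lower, while their list had a median of -0.06 over 26 members (17.9th percentile, between -0.09 and 0.03 under the alternatives) and UMPS was 2.21-fold higher. Detoxification genes had 3 members at least 2-fold higher and 4 at least 2-fold lower, including MGST1 at 2.92-fold higher and UGDH at 2.92-fold lower. Their median of -0.18 (1.55th percentile) did not stand apart under 4 of 8 alternatives, and was -0.03 without a filter. With the floor it was -0.03 as well (9.72th percentile). Apoptosis inhibitors had a median of -0.03 (between -0.10 and 0.06 under the alternatives) and a mean of 0.56 over 17 members (0.49 with the floor), the sign of the mean resting on TNFRSF11B, BCL2A1 (4.36-fold higher) and the decoy receptor TNFRSF10D (3.33-fold higher). Apoptosis promoters had a median of -0.15 (6.2th percentile, between -0.16 and -0.02 under the alternatives), with BCL2L11 (BIM) 3.72-fold and the death receptor FAS 2.08-fold lower. The weakest of the 5 BCL2L11 probe sets differed by -0.11, and 1 FAS probe set lay at or below 4.77 on both arrays.

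Of the signalling lists, 3 stood apart low, those of proximal immunoreceptor genes, growth factor receptors and ligands, and TGF-beta targets. Proximal immunoreceptor genes had a median of -0.26 over 16 members (1.95th percentile), with the Src-family kinase FYN at least 2.30-fold higher and YES1 2.23-fold lower, and the list no longer stood apart with the median over probe sets (2.89) and had a median of -0.14 without a filter. NF-kappaB targets had a median of -0.10 over 23 members (between -0.12 and 0.05 under the alternatives) and a mean of 0.09 that turned to -0.03 with the floor, with PTGS2 at least 13.5-fold higher, the chemokines CXCL8 at least 1.45-fold and CCL2 2.62-fold higher, and CCL5 8.16-fold and, named after its value was seen, CSF1 2.41-fold lower. MAPK output had a median of 0.03 (47.3th percentile, between -0.05 and 0.11 under the alternatives), with EREG, an EGF receptor ligand, 4.18-fold higher (its other probe set at or below 4.77 on both arrays). Growth factor receptors and ligands had 24 of 33 members below 0 and a median of -0.31 (0.06th percentile), with IGFBP7 4.78-fold and PDGFA 2.94-fold lower and EREG higher. TGF-beta targets had a median of -0.38 over 19 members (0.14th percentile), with SMAD6 at least 5.36-fold lower (its other probe set at -0.49) and ID2 at least 3.07-fold higher. The TGF-beta median was -0.22 with the mean over probe sets and -0.25 without a filter and with the floor, and with the median over probe sets, at -0.13, the list did not stand apart (9.23th percentile). Wnt targets had a median of -0.17 over 17 members and a mean of 0.06 that turned to -0.06 with the floor, with LEF1 at least 12.7-fold and TNFRSF19 at least 1.54-fold higher, and FZD7 4.97-fold and DKK3 4.09-fold lower. That list did not stand apart, but did so low with the median over probe sets (-0.24) and with the filter at the 75th percentile (-0.38). YAP and TAZ targets had a median of -0.11 (11.2th percentile), with DLC1 at least 2.20-fold lower and AMOTL1 at least 2.26-fold higher. That median lay between -0.24 and -0.09 under the alternatives, and the list did not stand apart in any.

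Control lists stayed close to 0. Of 33 ribosomal protein genes 0 passed 2-fold, with a median of 0.08 (94.5th percentile) and RPS15, among the brightest, at 0.17. Of 18 housekeeping genes 0 passed 2-fold, with a median of -0.02 (between -0.08 and 0.08 under the alternatives) and a mean of 0.02. The bright EEF1A1 and PPIA differed by -0.02 and -0.04, and PGK1 differed most, at 1.57-fold lower. Of the 44 lists scored, 22 stood apart, 18 low and 4 high, against 2.2 expected for lists of unrelated genes. Some lists share members, such as TGF-beta targets and extracellular matrix (4) and ABC transporters and antigen presentation (2). The 22 calls are therefore not independent.

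**Figure D3:**
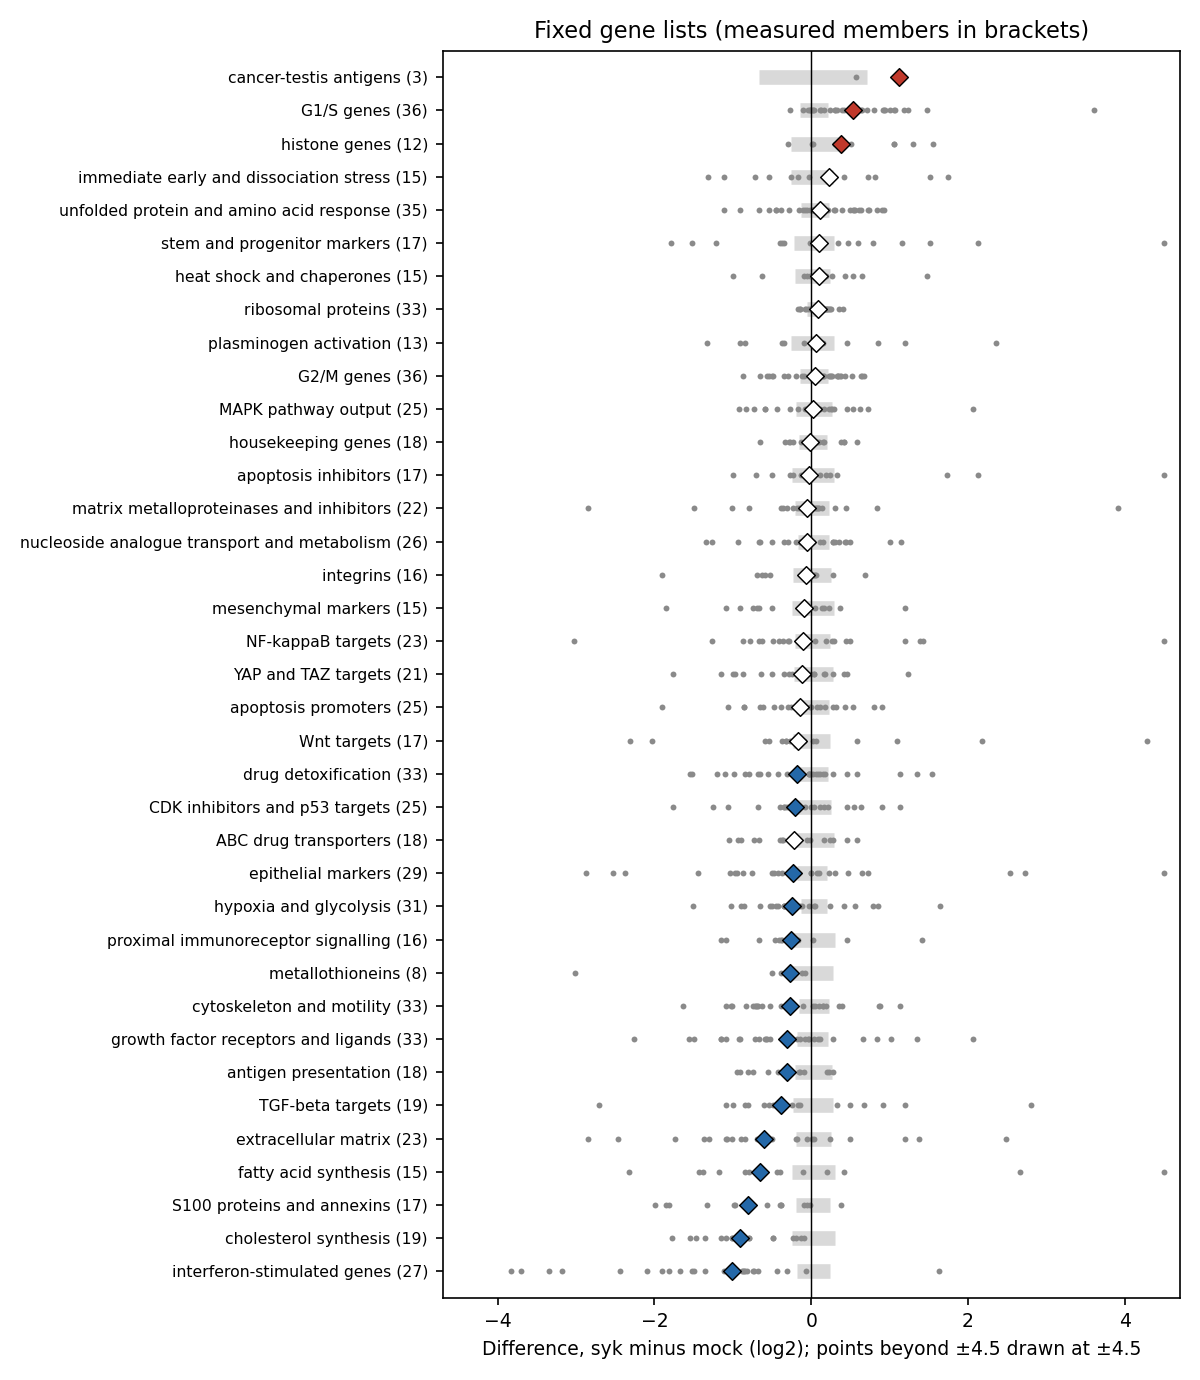
Differences syk minus mock (x axis, log2) for the fixed lists with at least 3 measured members, cell type markers left out. Small grey points are genes, drawn at the axis limit where they lie beyond it, diamonds are list medians, filled where the list stood apart (blue low, red high) and open where it did not, and grey bars span the central 95% of 10000 random lists matched on brightness. Interferon-stimulated genes (-1.01) and cholesterol synthesis (-0.90) have the lowest medians, and among lists with over 3 members G1/S genes (0.54) the highest.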

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

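The test in this part was chosen only after the differences between the arrays had been seen. Probe sets that could not be assigned to a single gene stayed out of the comparisons above. Of 4244 such probe sets past the brightness filter, 72 were at least 2-fold higher on the syk array and 123 at least 2-fold lower, together 4.59% of them, and the 72 were flagged because their signal lay above that of the mock array. Among the 3123 that the annotation used here does not list, the 2 furthest above the mock level were 5.95-fold higher (5.37 on mock and 7.94 on syk) and 5.54-fold higher, and the 2 with the lowest measured differences were at least 10.2-fold lower (8.12 on mock and 3.51 on syk) and at least 1.93-fold lower, bounded as in the report by the highest bacterial control. No group of this design had enough arrays to look for an outlying sample or for an effect that differs between groups.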

How the results depend on the processing

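The count of genes past 2-fold, 930 (462 higher and 468 lower on the syk array), was 562 (284 and 278) with the mean over probe sets, 486 (220 and 266) with the filter at the 75th percentile, 2904 (1557 and 1347) at 1.5-fold and 297 (144 and 153) at 3-fold. Under the filter at the 75th percentile all 486 were among the 930, since that filter only removes dimmer genes. With the mean over probe sets 529 of the 930 stayed past 2-fold in the same direction. Under the other 6 alternatives the counts stayed within 1.5 times. No scaling moved the share of higher genes by over 10 percentage points (49.7% as reported, 52.9% after median centring, 48.2% after loess). The SYK difference of 0.46 was 0.48 after median centring and 0.49 after loess. Neither scaling could move these values far, since median centring shifted the differences by 0.02 and the largest loess correction was 0.05. Their stability is therefore no separate evidence. Of 22 lists that stood apart, 10 did so in the same direction under all 8 alternatives, or all 7 that left enough members for the last named: interferon-stimulated genes, cholesterol synthesis, extracellular matrix, S100 proteins and annexins, cytoskeleton and motility, growth factor receptors and ligands, hypoxia and glycolysis, G1/S genes, histone genes and islet endocrine markers. Without a filter the median of fibroblast and stellate markers turned to 0.026 and that of ductal markers to 0, because members at background entered. Mesenchymal markers, ABC transporters and Wnt targets stood apart low under 3, 3 and 2 of the 8 alternatives, and the cause was not tested. With both arrays floored at the highest bacterial control, added after the data had been seen, 823 genes passed 2-fold (395 and 428), and 20 of the 22 lists still stood apart, detoxification genes and islet markers being the exceptions. Over 339 list values, 324 moved by less than the SD between probe sets (0.35). That SD exceeds many of the list medians, so such a list could lose its whole shift and still count as unmoved. Over 821 values of the named genes alone, under 5 alternatives, 693 moved by less than that SD, with 0 changes of sign in those past 2-fold. Those named for the largest differences had been chosen for the same sign in all their probe sets, so the lack of sign changes was largely built in. The alternative for a linear table was not run, since the values are logs. The neighbour settings in the next part were added after the data had been seen. No paired analysis was possible because each population has 1 array. With no replicate, none of these alternatives bears on variation between cultures, and dim probe sets limit the folds of genes absent or nearly absent on 1 array.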

Other observations

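The gene lists in this part were fixed beforehand. Every test of the 3 patterns below was chosen after the differences had been seen, the tests on neighbouring genes included.

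Further fixed lists added other biology. Hypoxia and glycolysis genes had a median of -0.24 over 31 members (0.12th percentile), with hexokinase 2, HK2, 3.14-fold higher and ALDOC at least 1.28-fold lower. Histone genes had a median of 0.38 over 12 members (98.7th percentile), with H2AC8 at least 2.05-fold and H1-2 2.46-fold higher, although histone genes resemble one another closely and probe sets can be shared. With probe sets ending in _at alone the histone median was 1.06. Of 3 measured cancer-testis antigens, MAGEA12 was 2.23-fold and PRAME 2.16-fold higher (median 1.11), and without a filter the list no longer stood apart (0.18, 97.3th percentile). The stem and progenitor list did not stand apart (median 0.10, between 0.03 and 0.14 under the alternatives), yet CXCR4 was at least 9.19-fold and SOX2 4.38-fold higher (1 of 3 SOX2 probe sets at or below 4.77 on both arrays), while NES was 3.46-fold lower. Immediate early genes went both ways, 8 of 15 above 0, with NR4A2 (at least 1.49-fold) and KLF4 (2.85-fold) higher and KLF2 (2.48-fold) and ATF3 (2.16-fold) lower. Their median of 0.22 (93.7th percentile) lay between -0.11 and 0.24 under the 8 alternatives (0.02 with the mean over probe sets), and the list did not stand apart under any of them. Metallothioneins were all below 0 (median -0.27, 2.06th percentile), of which MT1M was past 2-fold lower (a log2 difference of -1.58 with the floor) and the rest under 2-fold, and 3 of 7 alternatives ended the list's call. With probe sets ending in _at alone too few metallothioneins were left to score, and cross-hybridisation among these related genes was not excluded. The unfolded protein and amino acid response (median 0.12, ATF3 2.16-fold lower) and heat shock genes (median 0.10, between 0.05 and 0.24 under the alternatives, HSPB8 2.78-fold higher) did not stand apart.

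Markers of other cell types were mostly dim. Leukocyte (7 of 19 measured, median 0.18, between 0.01 and 0.23 under the alternatives), endothelial (5, median -0.003), acinar (3, median -0.13, mean 0.07, a median between -0.13 and 0.25 under the alternatives) and erythroid markers (2, median -0.03) had 0 members past 2-fold. Fibroblast and stellate markers had a median of -0.91 over 4 members, 3 of which are also in the mesenchymal list, with FBLN1 2.35-fold lower although 1 of its 4 probe sets lay at or below 4.77 on both arrays. Ductal markers had a median of -0.65 over 6 members, 3 of which are also in the epithelial list, with KRT19 2.72-fold (its other probe set at or below 4.77 on both arrays) and MUC1 2.06-fold lower and SLC4A4 at least 1.83-fold higher. Fibroblast and ductal markers each lost their call under 2 alternatives, no filter among them. Of 4 islet markers CHGB (at least 1.87-fold) and ISL1 (at least 1.31-fold) were higher (median 0.56, and 0.23 without a filter), a call that the floor at the highest bacterial control ended (0.20, 96.0th percentile), and 4 neural markers were lower by under 2-fold (median -0.57), a call that 4 of 7 alternatives ended.

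The first pattern is that SYK signal stayed low on the array labelled syk. A swap of the 2 labels would put the higher SYK signal on the mock array, and the brightest probe set was 0.46 higher on the syk array, too little to decide. A candidate explanation is that the probe sets miss the introduced cDNA, since 0 SYK probe sets lay above the 75th percentile of the syk array. Low expression in the population at harvest would look the same. Probe positions were not analysed here, which keeps all of these open.

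The second pattern is the lower level of interferon-stimulated genes. For a brightness trend between the arrays, the largest loess correction of any probe set was 0.05. Its removal could therefore hardly move the list median (-1.03, against -1.01 before), and that stability is no separate evidence. The small size of the trend itself argues against it as the whole cause. Unequal RNA integrity stays open: 23 of 27 members were lower by more than the 5' ACTB control probe set (-0.67), but the positions of probes along the transcripts were not analysed here. Whether the introduced kinase lowers these genes cannot be told apart from a difference that arose between 2 separately selected populations, since the median of -1.01 rests on 1 population of each kind.

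The third pattern is that neighbouring genes shifted together. In order along the autosomes of GRCh38.p14, medians over windows of 50 genes had an SD of 0.145, above the highest of 200 shuffled orders (0.082). Windows past the highest shuffled one (0.43) formed 5 runs: ZMYND11 to HNRNPF (116 genes, median -0.41), USP14 to SNRPD1 (54, -0.44), KCTD9 to FNTA (75, 0.36), SLC23A2 to VSX1 (57, 0.43) and CRYBB2P1 to SFI1 (58, 0.48). The runs depend on the settings. In 10 other draws of 200 shuffles there were between 5 and 10 runs, windows of 100 genes gave 9 runs, and windows of 25 genes gave 0.

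A first form of a held-out test set windows of 25 odd-numbered genes against their own shuffles and found 0 runs (highest window 0.53, just under the highest shuffled one), so it was replaced by blocks of 50 genes after that result. Across 238 blocks, medians of odd-numbered and of even-numbered genes correlated at r = 0.64 across blocks, which are not replicates. In the 60 blocks whose odd genes lay furthest from 0, 62.0% of the 1367 even genes under 2-fold went their block's way. The 95% exact binomial interval, 59.3% to 64.5%, treats genes as independent, although neighbours shifted together. The shift was thus shared by held-out genes under 2-fold. Blocks were picked by medians, which a few strongly changed neighbours can hardly move, so the share is no test of that explanation. Of the 60 blocks, 17 (28.3%) had even-gene medians outside the central 95% of random lists matched on brightness, which argues against brightness. The share of even genes going their block's way was 65.2% in the 24 furthest blocks, 60.0% in 119 and 54.9% over all 238. Over all 238 the lower bound of 53.6% no longer passes the 55% set for the test. A candidate explanation is a difference in DNA copy number between the populations over some stretches, which the 62.0% goes with, but it was found and tested on the same arrays, and regional regulation of expression was not separated from it.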
